A study of Mus musculus with 2 samples.

How the data were processed

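Single-cell RNA was measured in 2 libraries of dissected corneoscleral tissue from CD1 mice, an outbred strain. Per the labels' protocols, eyes were dissected in Ames' medium, the tissue was digested with papain and triturated, and droplet libraries were made with 10x Genomics Chromium 3′ chemistry of version 3. The deposited table holds raw UMI counts per gene and cell (a UMI is a tag that marks one captured RNA molecule), with no normalization. Cell Ranger 3.0.2 and the mouse genome build mm10 are named per the submitters' processing notes; the annotation and the filter that chose the barcodes are not given in the sources used here. In the deposited counts every barcode has over 1000 genes detected, with a minimum of 1001, so shallower cells had already been left out. The table lists 31053 genes by symbol and 5067 barcodes, 1352 in library 1 and 3715 in library 2, below the recovery of about 6000 cells that the labels state. Library 1 holds 7380341 UMIs, with a median of 3878.5 UMIs and 1652.5 genes per barcode, and library 2 holds 27681331 UMIs, with a median of 5542 UMIs and 2242 genes.

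Both libraries carry the same labels and form 1 group of 2 replicates. Nothing in the labels says whether they came from separate animals or from pools. The p-values measure only the spread between these 2 libraries that remains within classes once the overall library difference is removed. That spread is estimated over all classes together, is drawn towards a value shared with other genes, and may be technical. Both held cells with Xist RNA alone (492 and 1484) and cells with Y-linked RNA alone (141 and 573), so each library holds tissue of both sexes and more than 1 animal. They are not copies of one library: a chi-square of their counts over 15009 genes came to 21.9 per degree of freedom. Across 10485 genes, which are not independent replicates, Pearson's r between the libraries' sums ranged from 0.704 in the canal-like class to 0.980 in the meshwork-like class.

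Cells were kept with at least 500 genes and at most 20% mitochondrial counts. The limit on genes removed no barcode and the mitochondrial limit removed 266. Scrublet, run per library with an expected rate of 0.05, called 30 doublets (0.592%), 3 in library 1 and 27 in library 2, and these were left out. The 4771 kept cells were 1268 and 3503. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave 23 clusters (scanpy 1.11.5, leidenalg 0.10.2, Python 3.11.15, seed 0, no batch correction).

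Genes were split by the parity of a hash of their symbol, so that genes tested between clusters had not defined them. The 15456 clustering genes include every cell type marker, and the 15597 held-out genes include every gene of the fixed lists. Genes of both sets are correlated, so the split removes this circularity only in part. Cell type markers (163, of which 162 are in the table) and 15 gene lists (291 genes, all in the table) were fixed before the data were examined; the rule that scores the markers was set afterwards. A cluster took the name of the class whose markers had the highest mean z score over clusters. It stayed unnamed with under 3 markers at a fold of 2 over other cells, or when its top 10 genes held more markers of another class, or when its cells were shallow and none of its markers was among the top 10. By this rule 19 clusters were named and 4 were not. Names end in "-like" because they rest on markers alone.

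Counts were summed per class and library. The 12 classes with at least 10 cells in each library gave 24 sums of 58563 to 8413548 counts. They entered 1 fit of edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM scaling and filterByExpr, with the library as a block because all classes of a library come from one dissociated suspension. The fit tested 10485 genes, 5269 of them held out, with 11 residual degrees of freedom. The 4 meshwork-like clusters were fitted alone (8 sums, 9700 genes, 4927 held out, 3 residual degrees of freedom). Each gene's spread also borrows from other genes, worth a median of 24.54 prior degrees of freedom for the classes and 27.03 for the clusters. Very small p-values, above all between clusters, therefore rest mostly on this shared spread. Adjusted p-values are Benjamini-Hochberg values over the held-out genes, and a gene was called at an adjusted p under 0.05. A contrast against several classes is against the mean of their logs, so a class without a gene weighs as much as a class full of it. Levels are CPM (counts of a class sum scaled to a common total), as mean ± SD with n = 2 libraries. Fold changes are on the log2 scale ± SE. The SE is the absolute fold change over the square root of the test's F value, not a separately estimated error. It need not show the gap between the libraries, least of all where some classes lack counts. A ratio against a class without counts is a lower bound from a floor of 3 counts over the class, and with 1 to 3 counts the ratio has an exact 95% interval. Such intervals, like the Clopper-Pearson intervals of shares, cover counting error only.

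The named genes follow a rule fixed before the data were examined. They are the 12 largest rises and falls (6 per meshwork-like cluster) among called genes with an absolute log2 fold change of at least 1, the same direction in both libraries and at least 50 CPM in the higher class, leaving out provisional symbols. To these come up to 4 members of each list with the smallest adjusted p, and glaucoma genes highest in the class described. An error in the code that applied the 50 CPM limit to the wrong class in the comparison with fibroblast-like cells was found and corrected after results had been seen; it had changed which falls were named there and no test. The lists cover glaucoma and eye pressure genes, interstitial matrix, basement membrane, matrix turnover, contraction, mechanosensitive and water or ion channels, Wnt, TGF beta and BMP, nitric oxide and endothelin, targets of pressure-lowering drugs, neural crest transcription factors, lymphatic and angiopoietin genes, dissociation and immediate early genes, complement and interferon, and cholesterol and retinoid handling. Each list was tested against the other held-out genes by limma's camera (3.58.1) with a preset correlation of 0.01 and again with an estimated one, adjusted over the 15 lists. Gene coordinates are those of GENCODE M21 on GRCm38 (mm10), matched by unique symbol. The strand setting of the counting is not given in the sources used here, so counts of antisense or overlapping genes, and of close paralogs, are uncertain.

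The tests were checked on simulated data, drawn from the real sums' means and sizes with 200 changed genes, 50 at each of 4 fold sizes. In 1 simulation all other genes were set to no difference, and in the other 1500 were and the rest kept their real difference. For the meshwork-like class against the others, 76% and 84% of the 2-fold changes were called in the respective simulations. In the first, on 10083 genes, 101 of 4835 unchanged genes were called, all of them as higher, with a median log2 fold change of 0.27. In the second, on 10161 genes, 23 of 1542 were called, 20 of them as higher. Against the fibroblast-like class, 60% and 76% of the 4-fold changes and 30% and 46% of the 2-fold changes were called (10170 and 10165 genes). In the canal-like against the vascular-like class, 26% and 42% of the 4-fold changes and 56% and 62% of the 8-fold changes were called (10101 genes in each). In meshwork-like cluster 6, 60% and 78% of the 2-fold changes and 92% and 96% of the 4-fold changes were called (9382 and 9484 genes).

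Alternatives fixed beforehand were other size factors, DESeq2 1.42.0, no filter on low counts, no library block, either library left out, doublets kept, at least 1000 genes per cell, Leiden resolutions 0.5 and 2, clustering on all genes, ComBat on library, at least 30 cells per sum, a fold threshold, and an estimated correlation for the lists. Added after the data had been seen were at least 1500 genes per cell, the 5% highest doublet scores left out, sums thinned to the smallest, unnamed clusters in the fit, single clusters or classes left out, and more scalings. Sums were first thinned with edgeR's thinCounts, whose variance came to 10.1 times the binomial one. Binomial thinning (1.01 times) replaced it after its result, 52 called genes, had been seen. RNA from other cells was present in every droplet population: Krt12, a keratin of corneal epithelium, had a UMI in 92.4% of cells of meshwork-like cluster 2, with a median of 3 UMIs.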

Results

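The front of the mouse eye drains its fluid through the trabecular meshwork, a porous tissue of matrix beams and contractile cells, into Schlemm's canal, a vessel with features of both blood and lymphatic endothelium. Resistance in this pathway sets eye pressure, the main treatable cause of glaucoma. Single-cell RNA was counted in dissected corneoscleral tissue of CD1 mice of 10 to 12 weeks in 2 libraries, and 4771 cells were kept, 1268 in library 1 and 3503 in library 2. Clusters were given cell type names from marker genes. Meshwork-like cells were then compared with all other classes and with their stromal neighbours, canal-like with vascular endothelium-like cells, and the 4 meshwork-like clusters with one another.

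Meshwork-like cells were the largest class, with the markers Chil1, Edn3, Crym and Inmt in clusters 2 and 5 (Chil1 in cluster 2 alone) and Tfap2b, Lypd1 and Rspo4 in clusters 1 and 6. They made up 43.1 ± 4.64% of cells (2130 cells; 39.8% in library 1 and 46.4% in library 2). Macrophage-like cells made up 7.86 ± 0.374%, non-pigmented ciliary epithelium-like cells 4.88 ± 2.14%, and smooth or ciliary muscle-like cells 4.84 ± 2.08%. Ocular surface epithelium-like cells were 3.29 ± 0.308%, fibroblast or keratocyte-like cells 2.32 ± 0.174% and pericyte-like cells 1.92 ± 0.411%. Corneal endothelium-like cells, which line the back of the cornea beside the meshwork, were 2.92% of library 1 and 0.571% of library 2. Vascular endothelium-like cells were 1.34 ± 0.330% and canal or lymphatic endothelium-like cells 0.687 ± 0.366%, 12 and 15 cells. Also found were cells like B cells (0.995 ± 0.155%), retinal pigment epithelium (0.966 ± 0.195%), T or natural killer cells (0.787 ± 0.220%) and non-myelinating Schwann cells (0.536 ± 0.0893%). Another 24.7 ± 1.96% (1211 cells) stayed unnamed, among them cluster 4 (451 cells), which scored highest as meshwork but had under 3 of its markers up. The meshwork-like share depends on the clustering: it was 23.1% at a Leiden resolution of 2 and 27.5% among cells with at least 1500 genes. At a resolution of 2 the unnamed share was 40.7%, and a melanocyte-like class appeared (320 cells, 6.33%). The muscle-like share was 10.8% at a Leiden resolution of 0.5 and 12.9% among cells with at least 1500 genes. Non-pigmented ciliary epithelium-like cells were 2.46% with clustering on all genes, and macrophage-like cells 4.66% at a Leiden resolution of 2. Vascular-like cells were 2.02% at a resolution of 0.5 and 2.01% with doublets kept, and no canal-like class was found in either. Some names are weak. The meshwork-like name rests on 3 or 4 markers per cluster, and no marker was up in all 4 clusters. Clusters 5 and 6 had 0 meshwork markers among their top 10 genes. Cluster 6 scored 0.719 as meshwork, near unnamed cluster 4 (0.666). The fibroblast or keratocyte-like class is cluster 12 alone, with Dpt, Pi16, Clec3b, Scara5, Mfap5 and Cd34 up. The keratocyte marker Kera was not up there but in unnamed cluster 9, so the class may hold few keratocytes. Most muscle-like cells (143 of cluster 11) held much of the pigment cell gene Dct, a median of 6325 CPM, and the melanocyte score of that cluster came close (1.22 against 1.31). The ciliary epithelium-like cells held Dct too, a median of 5858 CPM, so they may not be free of pigmented cells. The B-like class held Xcr1, a dendritic cell receptor (132 ± 6.62 CPM), and it was replaced by a dendritic-like class with clustering on all genes or with at least 1500 genes per cell.

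**Figure D1:**
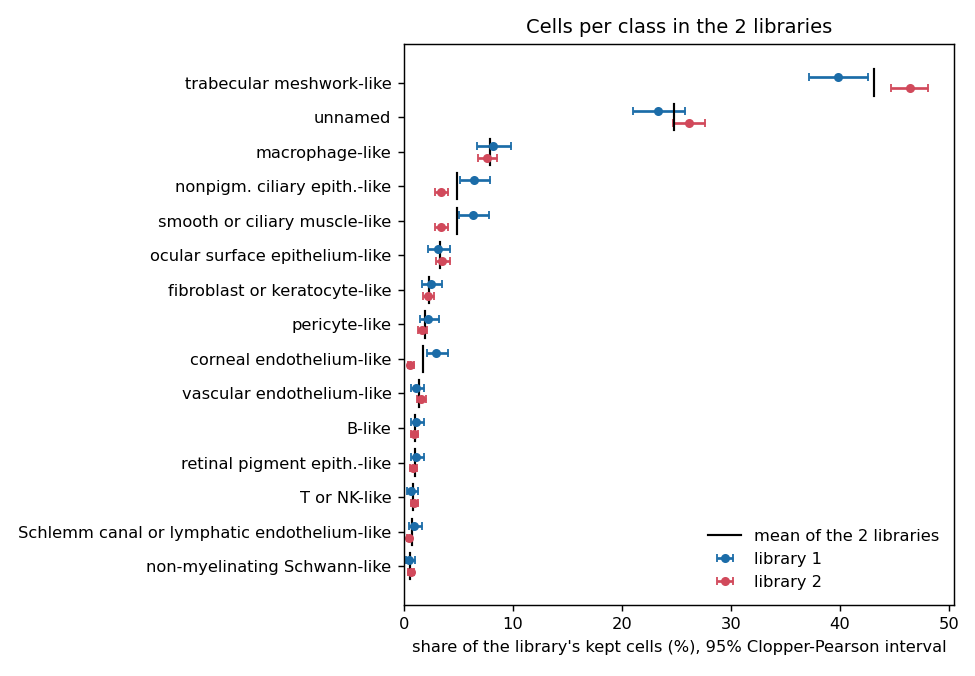
Share of kept cells (percent) in each class, with 1 dot per library, its exact 95% interval, and a black line at the mean of both libraries. Meshwork-like cells made up 43.1% and canal or lymphatic-like cells 0.687% on average.

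Against the mean of the 11 other classes, meshwork-like cells held more Rbp4, the plasma carrier of retinol, and more Ptn, a heparin-binding cytokine. They also held more Wnt6, a Wnt ligand, and Lum, a proteoglycan that spaces collagen fibrils. Higher too were Adra2a, the receptor through which alpha-2 agonists such as brimonidine lower eye pressure, and Cyp1b1, an enzyme mutated in congenital glaucoma. They were low in Ednrb, an endothelin receptor, and in Pdgfa, a growth factor for mesenchyme. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1623 of 5269 held-out genes differed, 1344 higher and 279 lower, and 985 of them by at least 1 on the log2 scale. With every sum thinned to the smallest, 209 were called.

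The higher share of these calls, 82.8%, depends on scaling, on the test and on the classes compared. It was 65.0% with DESeq2 and 68.9% after meshwork-like sums were rescaled to a median fold change near 0. With at least 30 cells per sum it was 63.7%, but that setting drops small classes such as the canal-like and vascular-like ones from the contrast. The median log2 fold change moved from 0.17 to 0.02 with that rescaling. The classes that the contrast averages include some without any count of a gene: all 618 calls were higher where the least-counted class had 0 counts, while 59 were higher and 39 lower where it had over 20. A gene that another class lacks tends to be higher in meshwork-like cells, so this split is set in part by the change itself.

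Rbp4 had the largest fitted rise, a log2 fold change of 6.29 ± 0.287 (191 ± 21.1 CPM in meshwork-like cells and a mean of 20.6 ± 10.9 in the others; adjusted p = 4.6e-18 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). It was higher in unnamed cluster 4 (283 CPM) and reached 114 ± 48.2 CPM in fibroblast-like cells. By ratio of mean CPM it lay below genes such as Adra2a, Ctxn3 and Wnt6. Ctxn3, a small membrane protein best known in kidney and brain, followed at 5.89 ± 0.222 (328 ± 34.4 and 18.7 ± 3.36 CPM), and Adra2a at 5.79 ± 0.301 (106 ± 10.9 and 6.02 ± 5.06 CPM). Ptn was the most abundant of the 12 at 3616 ± 271 CPM (5.33 ± 0.253), and Lum reached 1829 ± 221 CPM (5.46 ± 0.260). Both depend on the library: Lum was at 9.23 in library 1 alone and 4.74 in library 2 alone, and Ptn at 6.96 and 4.93. The small SEs of these 2 folds do not show such gaps, and the SEs of the other folds need not show them either. Wnt6 (5.10 ± 0.248), Cyp1b1 (5.25 ± 0.360), Itgbl1, an integrin-like secreted protein (5.11 ± 0.272), Tnmd, a tendon membrane protein (5.68 ± 0.378), Adgrl3, an adhesion receptor (5.70 ± 0.385), and Col11a1, a fibrillar collagen (5.47 ± 0.350), complete the group with Tnfaip6, a hyaluronan-binding protein (5.43 ± 0.530), which DESeq2 did not call. For Lum fibroblast-like cells were level (1796 ± 7.67 CPM), so its fold comes from the classes that lack it. The same holds for Cyp1b1, and Col11a1 was near in ciliary epithelium-like cells (82.8 CPM). The fold of Tnfaip6 rests on averaging logs over classes, since its CPM was 70.1 ± 57.3 against a mean of 53.4 ± 25.3, with 566 in fibroblast-like cells. The deepest falls were Creb5, a transcription factor, at -3.25 ± 0.628 (2.34 ± 1.70 and 54.2 ± 15.9 CPM; most in fibroblast-like cells), and Nxn, a thioredoxin family oxidoreductase, at -3.19 ± 0.285. Ednrb was lower at -2.17 ± 0.593, 5.04 ± 0.437 CPM against a mean of 171 ± 9.74, much of it from corneal endothelium-like cells. It was not called with at least 30 cells per sum, and Creb5 and Nxn were not called when clusters came from all genes. Creb5 was also lost when the 5% highest doublet scores were left out. Tspan13, a tetraspanin (-2.91 ± 0.364), Efhd2, a calcium-binding protein (-2.34 ± 0.251), Pdgfa (-2.08 ± 0.289) and Chchd10, a mitochondrial protein (-2.09 ± 0.295), were lower too. With every sum thinned to the smallest, Tspan13, Ednrb and Chchd10 were not called.

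Matrix genes were the clearest group. Of 29 interstitial matrix genes 27 were higher (28 with p adjusted over the list alone; camera adjusted p = 2.3e-16, adjusted p = 0.021 with an estimated correlation). Bgn, a small proteoglycan, was at 3.20 ± 0.171, Fbln1, an elastic fibre protein, at 4.22 ± 0.244, and Col3a1 at 3.85 ± 0.232. Among 15 basement membrane genes 12 were higher (12 over the list alone; camera adjusted p = 1.1e-04, 0.040 with an estimated correlation). Nid1, a laminin linker, stood at 3.60 ± 0.209 and Lama2 at 3.47 ± 0.228. Of 16 matrix turnover genes 12 were higher (13 over the list alone; camera adjusted p = 2.0e-06, 0.021 with an estimated correlation). Serpine2, a protease inhibitor, led at 4.85 ± 0.157 (2054 ± 81.9 and 186 ± 66.8 CPM), ahead of Adamts4 (4.16 ± 0.283) and Ctsk, cathepsin K (2.48 ± 0.182). Neural crest transcription factors were higher in 9 of 12 cases (11 over the list alone; camera adjusted p = 6.9e-07, 0.021 with an estimated correlation). Zfhx4 was at 3.29 ± 0.182, Eya2 at 3.83 ± 0.213 and Twist1 at 3.49 ± 0.265.

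Of 17 Wnt pathway genes 10 were higher and 1 lower (the same over the list alone; camera adjusted p = 5.5e-04, 0.026 with an estimated correlation). Dkk2, a Wnt antagonist, was at 4.34 ± 0.224 and Rspo2, a Wnt enhancer, at 4.84 ± 0.334. TGF beta and BMP genes were higher in 14 and lower in 1 of 23 (the same over the list alone; camera adjusted p = 0.0044, 0.046 with an estimated correlation). Id3, a BMP response gene, was at 2.62 ± 0.247 and Gdf10, a BMP family ligand, at 4.93 ± 0.339. Of 13 targets of pressure-lowering drugs 7 were higher and 1 lower (9 and 1 over the list alone; camera adjusted p = 0.0044, 0.040 with an estimated correlation). Adra2a and the prostaglandin E receptors Ptger1 (5.03 ± 0.375) and Ptger4 (3.24 ± 0.293) were higher. Ptger2 (5.77 ± 0.519) was higher as well but not called by DESeq2.

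Another 6 lists passed camera with the preset correlation but not with an estimated one. Contractile genes were higher in 10 and lower in 1 of 17 (11 and 1 over the list alone; camera adjusted p = 0.0037, adjusted p = 0.12 with an estimated correlation). Mylk, myosin light chain kinase, was at 2.05 ± 0.272. Tagln, a smooth muscle actin-binding protein, was called at 2.86 ± 0.400 although its CPM was below the mean of the others (910.4 ± 50.5 and 1233 ± 125), because pericyte-like and muscle-like cells hold most of it and the contrast averages logs. Its call was lost among cells with at least 1500 genes. Glaucoma genes were higher in 20 and lower in 1 of 39 (22 and 1 over the list alone; camera adjusted p = 4.0e-04, adjusted p = 0.084 with an estimated correlation). Angpt1 was among the members with the smallest adjusted p. Dissociation genes were higher in 14 of 18 (15 over the list alone; camera adjusted p = 0.0024, adjusted p = 0.29 with an estimated correlation). Fos was at 1.52 ± 0.218 and Junb at 1.41 ± 0.214. Nitric oxide and endothelin genes were higher in 6 and lower in 1 of 10 (the same over the list alone; camera adjusted p = 0.029, adjusted p = 0.084 with an estimated correlation). The guanylate cyclase subunit Gucy1a1 was at 2.52 ± 0.262 and the receptor Ednra at 4.24 ± 0.395. Cholesterol and retinoid genes were higher in 8 and lower in 1 of 15 (the same over the list alone; camera adjusted p = 0.037, adjusted p = 0.18 with an estimated correlation). Apod was at 3.46 ± 0.268. Complement genes were higher in 9 and lower in 1 of 17 (9 and 2 over the list alone; camera adjusted p = 0.043, adjusted p = 0.19 with an estimated correlation). Serping1, the C1 inhibitor, was at 3.05 ± 0.164. Lymphatic and angiopoietin genes (6 higher of 15, the same over the list alone; camera adjusted p = 0.20) and mechanosensitive and channel genes (4 higher and 2 lower of 12, the same over the list alone; camera adjusted p = 0.35) did not pass as lists. Their members Nrp2, a semaphorin receptor (2.65 ± 0.157), and Slc12a2, an ion cotransporter (2.25 ± 0.183), were higher.

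**Figure D2:**
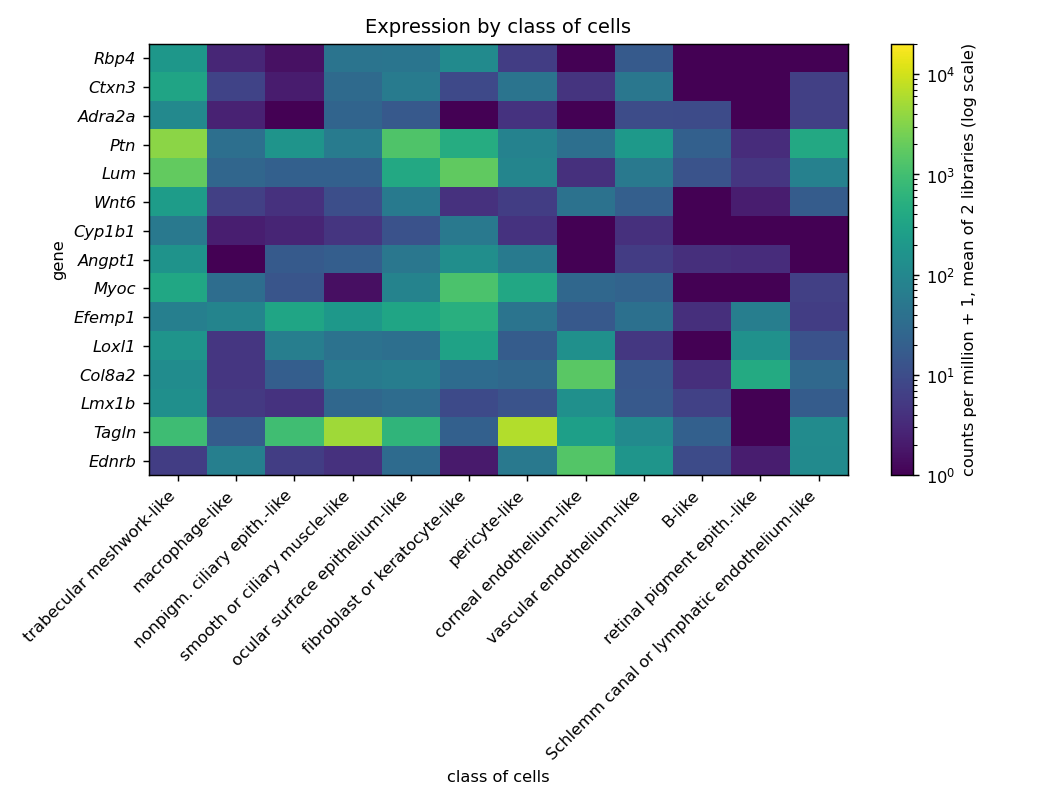
Expression (CPM + 1 on a log colour scale, mean of 2 libraries) of 15 genes across 12 classes. Rbp4, Ctxn3, Adra2a and Wnt6 are higher in meshwork-like cells, and Ednrb is low there (5.04 CPM).

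Next to the fibroblast or keratocyte-like class, meshwork-like cells held more Tagln, an actin-binding protein, and Mylk, the myosin light chain kinase. As a class they also held much more Wnt6 and Adra2a, though their cluster 2 held little Wnt6. Fibroblast-like cells held more Fn1 (fibronectin), Fbn1 (fibrillin, the scaffold of elastic microfibrils), Mmp2 (a gelatinase) and C3, the central complement protein. No gene list was called here when camera estimated the correlation between genes. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 820 genes differed, 402 higher and 418 lower in meshwork-like cells, and 148 with every sum thinned to the smallest.

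Adra2a had no count in fibroblast-like cells, a ratio of at least 21.9-fold at a floor of 3 counts over the class. On the same floor Atp1b2, a sodium pump subunit, differed by at least 18.1-fold, Alpl, alkaline phosphatase, by at least 13.5-fold, and Adgrl3 by at least 12.4-fold. Wnt6 had 2579 and 3 counts, a ratio of 53.1 (95% counting interval 18.1 to 258), and Cntn1, a neural adhesion protein, 1083 and 1, a ratio of 66.8 (12.0 to 2643). Neither ratio holds for every meshwork-like cluster: fitted separately, cluster 2 held Wnt6 at 7.06 ± 3.75 CPM and Cntn1 at 3.63 ± 2.02 CPM. Alpl was not called at a Leiden resolution of 2, nor Cntn1 with every sum thinned. Ctxn3 was higher at 5.28 ± 0.463 (328 ± 34.4 and 7.81 ± 0.757 CPM; adjusted p = 9.4e-11 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and Ogfrl1 at 5.29 ± 0.532. The largest falls included Dact2, a Wnt modulator, with 2 and 59 counts (a ratio of 478 towards fibroblast-like cells, 95% counting interval 127 to 4039), and Emilin2, an elastic fibre glycoprotein, at -7.84 ± 0.613. Meox2, a mesodermal homeobox gene, was lower at -7.39 ± 0.410 (1.39 ± 0.290 and 271 ± 23.5 CPM), Sfrp2, a secreted Wnt antagonist, at -7.38 ± 0.304 (6.56 ± 0.753 and 1021 ± 85.2 CPM), and Creb5 at -7.18 ± 0.401. Ly6a, a surface antigen of mesenchymal progenitors, was abundant in fibroblast-like cells (45.4 ± 11.9 and 2850.1 ± 622 CPM; -5.97 ± 0.310). Adgrd1, an adhesion receptor with 2 and 43 counts (a ratio of 348, interval 90.7 to 2968), and Prg4, lubricin (-5.96 ± 0.523), were lower too but not called by DESeq2. Tek (-5.94 ± 0.586) was not called with every sum thinned.

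Interstitial matrix genes were lower in 17 and higher in 3 of 29 (17 and 4 over the list alone; camera adjusted p = 2.0e-07, adjusted p = 0.20 with an estimated correlation). Col14a1 was at -5.40 ± 0.245, Fbln2 at -4.20 ± 0.266, Fbn1 at -3.32 ± 0.303 (105 ± 2.88 and 1052 ± 76.8 CPM) and Fn1 at -3.47 ± 0.361. From the matrix turnover list, Mmp2 was lower at -3.32 ± 0.238. Contractile genes were higher in 9 and lower in 1 of 17 (10 and 1 over the list alone; camera adjusted p = 2.3e-05, adjusted p = 0.20 with an estimated correlation). Tagln was at 5.09 ± 0.734 (910.4 ± 50.5 and 19.8 ± 28.0 CPM), Mylk at 4.23 ± 0.592 and Tpm2, a tropomyosin, at 2.73 ± 0.364. Dissociation genes were higher in 8 of 18 (the same over the list alone; camera adjusted p = 0.0090, adjusted p = 0.62 with an estimated correlation). Btg2 was at 1.90 ± 0.320 and the heat shock gene Hspb1 at 1.97 ± 0.394. Complement genes were lower in 6 and higher in 2 of 17 (the same over the list alone; camera adjusted p = 0.036, adjusted p = 0.49 with an estimated correlation). C3 was at -6.35 ± 0.417, Cd55, a complement brake, at -5.90 ± 0.416 and Serping1 at -1.79 ± 0.220. Glaucoma genes split into 11 higher and 12 lower. Efemp1, a fibulin (-2.77 ± 0.227), Cdkn1a, a cell cycle inhibitor (-2.62 ± 0.307), and Myoc (-1.68; 367 ± 118 and 1229 ± 647 CPM) were lower. The fibroblast-like class is small (108 cells), and in simulated data only 60% to 76% of 4-fold changes were recovered.

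**Figure D3:**
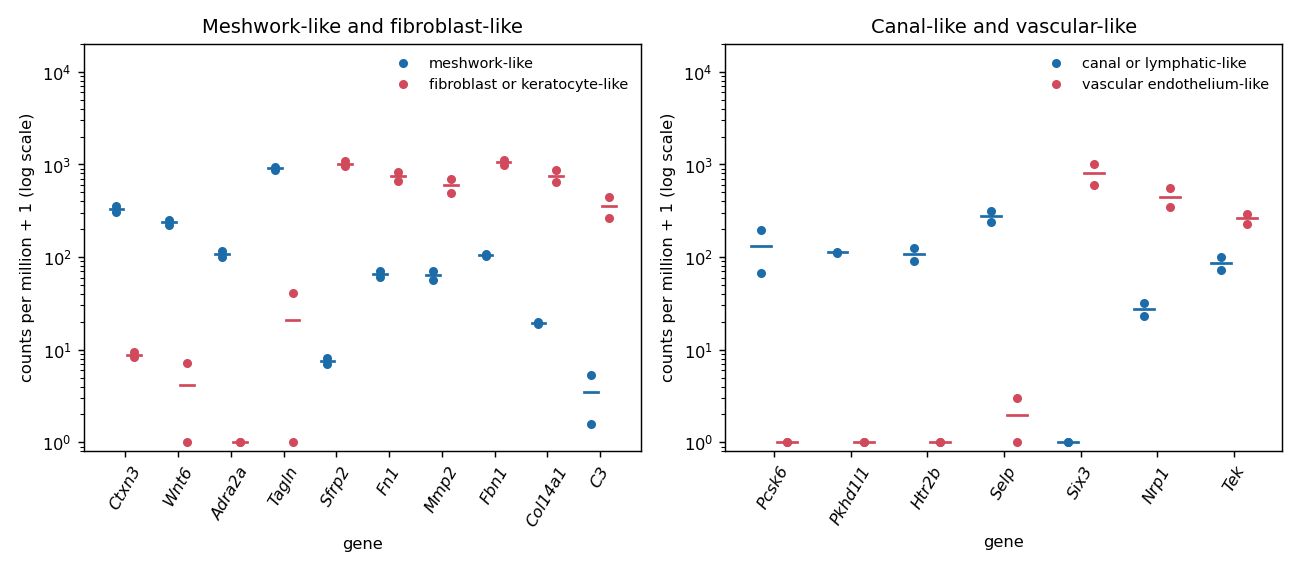
Left, 10 genes in meshwork-like and fibroblast or keratocyte-like cells; right, 7 genes in canal or lymphatic-like and vascular endothelium-like cells, as CPM + 1 on a log axis with a dot per library and a line at the mean. Tagln is higher and Fn1 and C3 are lower in meshwork-like cells, and Six3 has no count in the canal-like class.

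The canal or lymphatic-like class, called canal-like for short, was set against vascular endothelium-like cells. Its marker list covers Schlemm's canal and lymphatic endothelium together, so which of these the class is stays open. It held more Selp, P-selectin, an adhesion receptor for leukocytes that marks venous endothelium, Sema3a, a guidance cue that shapes lymphatic valves, and Timp2, an inhibitor of matrix proteases. Vascular-like cells held more Six3, a homeobox gene of eye and forebrain development, and Nrp1, a coreceptor of vascular growth factor. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 183 genes differed, 82 higher and 101 lower in the canal-like class, and 98 with every sum thinned. DESeq2 called 135 genes and turned the split to 61.5% higher from 44.8%.

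Pcsk6, a protease that matures growth factors, was higher, with 131 ± 90.9 CPM and no count in vascular-like cells, at least 28.4-fold at a floor of 3 counts over the class (adjusted p = 1.2e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Pkhd1l1 (112 ± 1.45 CPM, at least 23.9-fold) and Htr2b, a serotonin receptor (106 ± 24.4 CPM, at least 22.7-fold), also lacked counts there, and Selp had 51 and 1 counts, a ratio of 175 (95% counting interval 29.9 to 7027). DESeq2 did not call Pkhd1l1, Htr2b or Selp. It did call Ifi27l2a, an interferon-induced gene (5.18 ± 0.631; 513 ± 538 and 5.91 ± 8.36 CPM; 11.53 in library 1 alone and 3.48 in library 2 alone), and Sema3a with 24 and 2 counts (a ratio of 41.1, interval 10.2 to 359). Timp2 was higher at 3.26 ± 0.345 (749 ± 118 and 66.8 ± 22.6 CPM), the laminin Lama4 at 2.55 ± 0.472 and the caveolar coat gene Cav1 at 1.40 ± 0.329. Cav1 was not called with every sum thinned. Lyve1, a lymphatic hyaluronan receptor, had 19 counts in the canal-like class, all in library 2, and its call was lost with DESeq2. Lymphatic and angiopoietin genes showed no net shift as a list (camera adjusted p = 0.41, and 0.41 with an estimated correlation). Single members did differ, with 3 higher and 3 lower of 15 (4 and 3 over the list alone). Among all 5269 held-out genes 183 were called. Camera tests a net shift only, so it says nothing about members that go both ways.

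Six3 was lower by at least 54.2-fold at that floor (no count in canal-like cells and 798 ± 284 CPM in vascular-like cells; adjusted p = 5.8e-10 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Rapgef4, a cAMP-regulated exchange factor, was lower by at least 6.16-fold, Lef1, a Wnt-responsive transcription factor, by at least 5.96-fold, and Nostrin, a nitric oxide synthase trafficking factor, by at least 5.28-fold. Tmem252, lower by at least 17.4-fold, was not called by DESeq2. Col17a1, lower by at least 7.33-fold, was not called by DESeq2, without the library block or with the 5% highest doublet scores left out. It is a hemidesmosome gene of epithelia, and 31.3% of the deep vascular-like cells (5 of 16) held RNA of both sexes, a sign of mixed droplets. Nrp1 was lower at -4.12 ± 0.481 and the water channel Aqp1 at -2.82 ± 0.544. Tek, the angiopoietin receptor needed for Schlemm's canal, was lower at -1.62 ± 0.456 but was not called with other size factors, without the block, with thinned sums or by DESeq2.

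As lists, TGF beta and BMP genes were lower in 4 of 23 (7 lower and 1 higher over the list alone; camera adjusted p = 0.0021, adjusted p = 0.27 with an estimated correlation). The BMP response gene Id1 was at -3.27 ± 0.550 and the receptor Bmpr2 at -1.83 ± 0.372. Contractile genes were lower in 2 of 17 (2 over the list alone; camera adjusted p = 0.0044, adjusted p = 0.40 with an estimated correlation). These were Rhob (-1.58 ± 0.292) and Tpm2 (-2.32 ± 0.571). Dissociation genes were lower in 2 of 18 (2 over the list alone; camera adjusted p = 0.0044, adjusted p = 0.41 with an estimated correlation). These were Ier2 (-1.83 ± 0.342) and Nr4a1 (-1.47 ± 0.382), but without the library block neither was called, and DESeq2 did not call Nr4a1. Tpm2 was not called with ComBat, with the 5% highest doublet scores left out or with thinned sums. With 27 canal-like cells the test is weak: 26% to 42% of simulated 4-fold changes were recovered.

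The 4 meshwork-like clusters differ in many genes, and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1539 genes in at least 1 of them. Cluster 6 held the most Acta2 (smooth muscle actin) and Tagln. At a Leiden resolution of 0.5 the muscle-like class grew from 198 to 526 cells, and the meshwork-like class fell from 2130 to 1848. Whether cells of cluster 6 took the muscle name there was not traced, so its contractile genes may not be a trait of meshwork. Cluster 2 held the most Chad, Thbs4 and Mgp, an inhibitor of calcification. Cluster 5 is marked by Ptn and by Hsd11b1, the enzyme that turns inactive glucocorticoid into its active form. Unnamed cluster 4 held at least as much of both, so neither is specific to cluster 5. Cluster 1 held the most Slc4a10, a bicarbonate transporter, and Cntn1. Counts of called genes depend on the model here, with 769 by DESeq2, 930 without the library block and 589 with every sum thinned, for the 4 clusters together.

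Cluster 1 (842 cells; 312 higher and 214 lower than the mean of the other 3) held Slc4a10 at 3.94 ± 0.281 (91.4 ± 44.2 and 18.1 ± 0.814 CPM; adjusted p = 6.0e-12 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Abcg5, a sterol transporter (3.76 ± 0.253), Cntn1 (3.24 ± 0.151) and Wnt6 (2.24 ± 0.140). Neither Slc4a10 nor Cntn1 was confined to it: cluster 6 had Slc4a10 at 51.6 ± 3.17 CPM, and cluster 5 had Cntn1 at 141 ± 56.6. For Wnt6 cluster 5 was close (361 ± 152 CPM against 397 ± 35.4), and cluster 2 was low at 7.06 ± 3.75. Adra2a was higher there at 1.85 and the sterol synthesis gene Hmgcs1 at 1.42 ± 0.114, while Myoc was lower at -3.11 ± 0.328 (34.4 ± 3.68 and 499 ± 96.5 CPM). Interstitial matrix genes were lower in 18 of 30 (19 over the list alone; camera adjusted p = 5.3e-13, adjusted p = 0.49 with an estimated correlation). Mgp was at -1.68 ± 0.160 and Col1a1 at -1.11 ± 0.103. Contractile genes were higher in 5 of 17 (6 over the list alone; camera adjusted p = 0.049, adjusted p = 0.49 with an estimated correlation). Lmod1, a leiomodin, was at 1.75 ± 0.235. TGF beta and BMP genes were lower in 5 and higher in 1 of 18 (6 and 1 over the list alone; camera adjusted p = 0.049, adjusted p = 0.57 with an estimated correlation). Id1 was at -1.79 ± 0.140.

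Cluster 2 (564 cells; 575 higher and 410 lower) held Col10a1, a cartilage collagen, with 106 ± 11.5 CPM and no count elsewhere in the meshwork-like cells, at least 229-fold at a floor of 3 counts, though DESeq2 did not call it. Foxd1, a stromal transcription factor, had 168 and 2 counts, a ratio of 189 (95% counting interval 51.5 to 1574), and Thbs4 (5.71 ± 0.354), Chad (5.70 ± 0.330) and Tspan11 (6.84 ± 0.328) were higher. Myoc reached 842 ± 219 CPM against 229 ± 24.6 (3.03 ± 0.224; adjusted p = 2.3e-12 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and Wnt6 was lower at -5.21 ± 0.233. Myoc was also high in cluster 6, at 559 ± 175 CPM. Interstitial matrix genes were higher in 21 of 30 (22 and 2 lower over the list alone; camera adjusted p = 2.7e-13, adjusted p = 0.27 with an estimated correlation). Mgp was at 2.56 ± 0.132 and Fbln1 at 2.19 ± 0.0967. Nitric oxide and endothelin genes were higher in 5 of 7 (7 over the list alone; camera adjusted p = 1.1e-05, adjusted p = 0.27 with an estimated correlation). Gucy1a1 was at 2.02 ± 0.132 and Ece1, which matures endothelin, at 1.52 ± 0.121. TGF beta and BMP genes were higher in 11 and lower in 2 of 18 (the same over the list alone; camera adjusted p = 0.0011, adjusted p = 0.42 with an estimated correlation). Gdf10 stood at 3.46 ± 0.152. Glaucoma genes were higher in 16 and lower in 7 of 32 (16 and 9 over the list alone; camera adjusted p = 0.0066, adjusted p = 0.42 with an estimated correlation). Angpt1 was at 2.57 ± 0.150. Mechanosensitive and channel genes were higher in 5 of 10 (5 and 1 lower over the list alone; camera adjusted p = 0.0066, adjusted p = 0.27 with an estimated correlation). Piezo2, a stretch-gated channel, stood at 2.39 ± 0.217. Neural crest transcription factors were higher in 7 and lower in 2 of 9 (the same over the list alone; camera adjusted p = 0.0066, adjusted p = 0.27 with an estimated correlation). Matrix turnover genes were higher in 8 and lower in 3 of 16 (9 and 3 over the list alone; camera adjusted p = 0.025, adjusted p = 0.33 with an estimated correlation). Timp3, a protease inhibitor, stood at 3.16 ± 0.127. Contractile genes were lower in 4 and higher in 1 of 17 (7 and 1 over the list alone; camera adjusted p = 0.031, adjusted p = 0.42 with an estimated correlation).

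Cluster 5 (383 cells; 466 higher and 343 lower) held Ptn at 17419 ± 4638 CPM against 881 ± 1.38 (5.02 ± 0.106; adjusted p = 3.9e-26 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The protease Adamts16 (7.74 ± 0.278), Hsd11b1 (5.39 ± 0.214; 223 ± 85.6 and 7.27 ± 3.15 CPM) and Wnt10a (4.97 ± 0.177) were higher with it, and so was Vcan, versican, at 3.59 ± 0.196. Tnmd had 1 and 677 counts, a ratio of 134 (95% counting interval 24.0 to 5305), and Acta2 was lower at -3.57 ± 0.180. Contractile genes were lower in 13 and higher in 2 of 17 (the same over the list alone; camera adjusted p = 1.0e-09, adjusted p = 0.22 with an estimated correlation). Tagln was at -1.78 ± 0.117. Cholesterol and retinoid genes were higher in 9 and lower in 1 of 13 (the same over the list alone; camera adjusted p = 3.1e-05, adjusted p = 0.17 with an estimated correlation). Aldh1a2, which makes retinoic acid, was at 2.64 ± 0.185. Basement membrane genes were higher in 10 and lower in 1 of 14 (10 and 2 over the list alone; camera adjusted p = 2.1e-04, adjusted p = 0.17 with an estimated correlation). Col15a1 was at 3.85 ± 0.201. Glaucoma genes were lower in 15 and higher in 4 of 32 (15 and 6 over the list alone; camera adjusted p = 0.011, adjusted p = 0.63 with an estimated correlation). Col11a1 stood at -2.08 ± 0.217. TGF beta and BMP genes were lower in 9 and higher in 3 of 18 (9 and 4 over the list alone; camera adjusted p = 0.035, adjusted p = 0.63 with an estimated correlation). Tgfb2 was higher even so at 1.66 ± 0.138.

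Cluster 6 (341 cells; 361 higher and 417 lower) held Acta2 at 1621 ± 225 CPM against 194 ± 45.6 (3.56 ± 0.109; adjusted p = 2.5e-21 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Tagln (2.49 ± 0.0900), Lmod1 (3.79 ± 0.194), Cav1 (3.56 ± 0.191) and Cdh23, a cadherin of hair cells (4.22 ± 0.310). Ptn was lower at -4.54 ± 0.167, Nostrin was absent (at least 36.5-fold lower at that floor), and the transcription factor gene Meox1 had 1 and 525 counts, a ratio of 121 (95% counting interval 21.6 to 4778). Contractile genes were higher in 11 and lower in 2 of 17 (12 and 2 over the list alone; camera adjusted p = 1.4e-13, adjusted p = 0.23 with an estimated correlation). Tpm2 was at 1.35 ± 0.0980. Nitric oxide and endothelin genes were lower in 6 of 7 (the same over the list alone; camera adjusted p = 1.3e-04, adjusted p = 0.33 with an estimated correlation). Gucy1a1 was at -1.22 ± 0.194 and Ednra at -1.67 ± 0.275. Dissociation genes were lower in 9 and higher in 2 of 18 (11 and 2 over the list alone; camera adjusted p = 5.2e-04, adjusted p = 0.38 with an estimated correlation). Cxcl1 was at -2.01 ± 0.126. Interstitial matrix genes were lower in 12 and higher in 6 of 30 (17 and 7 over the list alone; camera adjusted p = 0.0043, adjusted p = 0.33 with an estimated correlation). Lum stood at -1.45 ± 0.104, with Fmod, fibromodulin, higher at 2.93 ± 0.179. Cholesterol and retinoid genes were lower in 7 and higher in 2 of 13 (8 and 3 over the list alone; camera adjusted p = 0.014, adjusted p = 0.33 with an estimated correlation). Aldh1a2 stood at -4.86 ± 0.326. Basement membrane genes were lower in 6 and higher in 3 of 14 (9 and 4 over the list alone; camera adjusted p = 0.037, adjusted p = 0.43 with an estimated correlation).

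**Figure D4:**
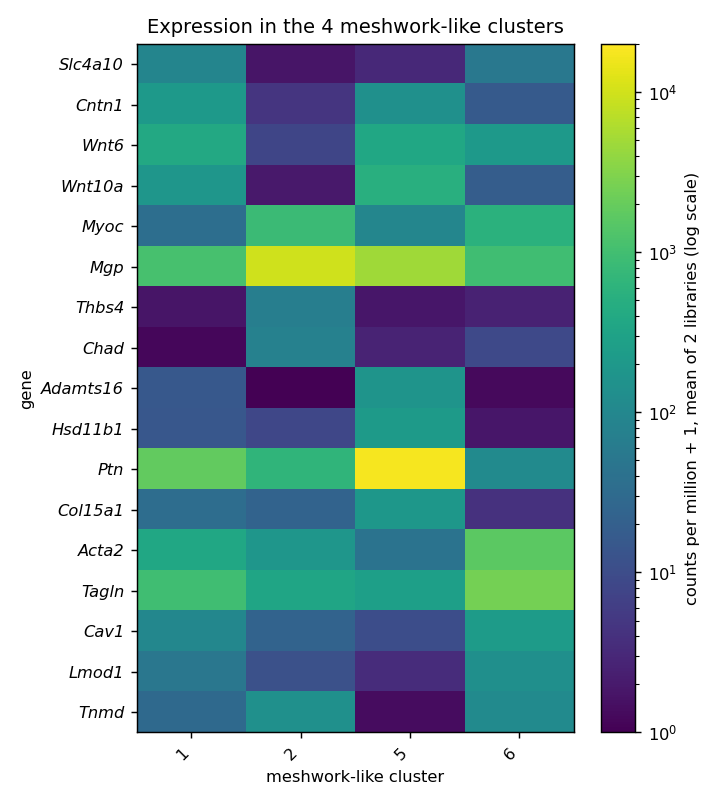
Expression (CPM + 1 on a log colour scale, mean of 2 libraries) of 17 genes across meshwork-like clusters 1, 2, 5 and 6. Ptn peaks in cluster 5 (17419 CPM), Acta2 in cluster 6 (1621 CPM) and Myoc in cluster 2 (842 CPM).

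The list of genes linked to glaucoma and eye pressure holds genes of open-angle glaucoma such as Myoc, which encodes myocilin, of developmental glaucoma such as Cyp1b1, and of the angiopoietin pathway such as Tek and Angpt1. Meshwork-like cells had the highest mean Cyp1b1 and Angpt1 of the classes, with fibroblast-like cells close behind in both. Within the meshwork-like class, cluster 2 held the most of both. Fibroblast-like cells led for Myoc and Efemp1, and corneal endothelium-like cells for Col8a2, a collagen of Descemet's membrane. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 38 of 39 measured genes were higher in at least 1 class than in the mean of the others. With every sum thinned, 18 were, 6 of them in meshwork-like cells. Genes of any kind are often called too: 353 to 1344 of 5269 held-out genes were higher in single classes. The share of all genes higher in at least 1 of the 12 classes was not counted. The 38 is therefore not a result about glaucoma genes in particular.

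Meshwork-like cells had 20 higher and 1 lower list genes (22 and 1 over the list alone), ocular surface epithelium-like cells 19 and 1 (21 and 2 over the list alone), fibroblast-like cells 18 higher (18 over the list alone), corneal endothelium-like cells 17 higher and 2 lower (18 and 2 over the list alone) and B-cell-like cells 3 and 8 (3 and 12 over the list alone). Non-pigmented ciliary epithelium-like cells had 13 and 5 (16 and 6 over the list alone), pericyte-like cells 12 and 2 (13 and 3), vascular endothelium-like cells 11 higher, and canal-like cells 6 higher and 1 lower (both the same over the list alone). The ocular surface-like count may come in part from mixed droplets, since 89.5% of cells of cluster 10 held Dcn, a stromal gene, and 23.7% of its deep cells held RNA of both sexes. The number of called genes of any kind differs between classes too: 1344 held-out genes were higher in meshwork-like cells, 1170 in ocular surface-like cells and 353 in canal-like cells. In corneal endothelium-like cells 892 were higher, in fibroblast-like cells 762 and in pericyte-like cells 582. Fibroblast-like cells thus had nearly as many higher list genes as meshwork-like cells from far fewer calls of any kind.

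By mean CPM, 5 list genes were highest in meshwork-like cells, among them Angpt1, the ligand of Tek (158 ± 14.2 CPM; 5.01 ± 0.273), Gmds, a fucose synthesis enzyme (103 CPM; 2.04), Col11a1 (103 ± 6.99 CPM) and Cyp1b1 (53.6 ± 17.0 CPM). For Cyp1b1 this is a tie with fibroblast-like cells (53.1 ± 27.9 CPM), and for Angpt1 they came near (133 ± 79.2 CPM). Fitted separately, meshwork-like cluster 2 held Angpt1 at 386 ± 55.5 CPM, and clusters 1, 5 and 6 at 48.7 to 107. Cyp1b1 was at 98.5 ± 10.2 CPM in cluster 2 and at 30.2 to 53.0 in those clusters. Corneal endothelium-like cells led for 6, among them Svep1, a ligand of the angiopoietin pathway (599 ± 87.6 CPM), Col8a2 (1606 ± 272 CPM), Angpt2 (199 ± 24.2 CPM) and Lmx1b (141 CPM). For Lmx1b the lead is over the meshwork-like class as a whole. In the separate fit, meshwork-like clusters 1 (193 ± 15.5 CPM) and 6 (246 ± 26.0 CPM) lay above that level. Clusters 2 (41.3 ± 3.95 CPM) and 5 (86.3 ± 7.36 CPM) lay below it. Fibroblast-like cells led for 6, with Myoc at 1229 ± 647 CPM and Efemp1 at 509 ± 176. Tek was highest in vascular-like cells (261 ± 45.8 CPM), Cav1 in canal-like cells (384 ± 20.9 CPM), Foxc1 in pericyte-like cells (428 ± 11.7 CPM) and Bmp4 in retinal pigment epithelium-like cells (409.8 ± 132 CPM). With the unnamed clusters in the fit, Myoc (3152 ± 1044 CPM) and Angptl7, a secreted protein whose loss lowers eye pressure (2136 ± 1191 CPM), were highest in cluster 9. So was Col11a1 (129 ± 31.9 CPM), and Gmds was highest in cluster 4 (147 ± 46.6 CPM). The source of these genes is not settled.

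Gene positions on GRCm38 (mm10) place Rbp4 (ENSMUSG00000024990) at chromosome 19 38116629 to 38125281 (minus strand). Ptn (ENSMUSG00000029838) lies at chromosome 6 36714929 to 36810220 (minus), and Adra2a (ENSMUSG00000033717) at chromosome 19 54044151 to 54048982 (plus). Wnt6 (ENSMUSG00000033227) lies at chromosome 1 74771892 to 74785322 (plus) and Acta2 (ENSMUSG00000035783) at chromosome 19 34241090 to 34255590 (minus). Myoc (ENSMUSG00000026697) lies at chromosome 1 162639155 to 162649693 (plus) and Six3 (ENSMUSG00000038805) at chromosome 17 85613608 to 85629302 (plus).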

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

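Of 287 named gene results, DESeq2 weakened 35, no library block 13, relative log expression factors 1 and no scaling 2, while rescaled meshwork-like sums weakened none of 239. Thinning every sum to the smallest weakened 39 of 199. At least 1000 genes per cell removed no cell and gave no value of its own. Without replicate 2, 117 of 287 stayed the same, 167 moved and 3 reversed, and without replicate 1, 37 moved. Moved means that the other library's value lay further from the joint fold than the SD of the 2 single-library values. This limit grows with the gap between libraries, so the label does not measure the gap. The counts show that the joint folds lie nearer library 2, the deeper one. Without a library no residual degrees of freedom are left, so there is no count of calls. There was no canal-like comparison with doublets kept, at a Leiden resolution of 0.5, with at least 1500 genes or with at least 30 cells per sum.

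Between meshwork-like clusters DESeq2 called 769 genes in place of 1539, and 185, 513, 350 and 338 in clusters 1, 2, 5 and 6 in place of 526, 985, 809 and 778. With no replicate block the counts were 930 in all and 198, 639, 415 and 395 by cluster, and camera called 5 lists in place of 3 between canal-like and vascular-like cells. In all 951 genes were called at a Leiden resolution of 2 and 1020 with at least 1500 genes per cell. The cause of these shifts was not tested.

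With every sum thinned to the smallest, 209 genes were called in meshwork-like cells against the others, 148 against fibroblast-like cells and 98 between canal-like and vascular-like cells. Between meshwork-like clusters 589 were called in all, and 130, 341, 276 and 297 by cluster. Of the glaucoma genes 18 stayed higher in some class and 6 in meshwork-like cells. The cause was not tested.

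An added log2 fold change of at least 1 left 985 genes in meshwork-like cells against the others, 800 between clusters in all, and 206, 482, 387 and 377 by cluster. The cause was not tested.

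With an estimated correlation camera called 7 of 13 lists in meshwork-like cells against the others. It called 0 of 4 against fibroblast-like cells, 0 of 3 between canal-like and vascular-like cells, and 0 of 3, 8, 5 and 6 in clusters 1, 2, 5 and 6; at an unadjusted p under 0.05 it had 2, 1, 0, 1, 3 and 1. The cause was not tested.

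The meshwork-like share was 43.1% and became 38.0% and 23.1% at Leiden resolutions of 0.5 and 2, 37.8% with ComBat on library and 27.5% with at least 1500 genes. The muscle-like share was 4.84% and became 10.8% at a resolution of 0.5 and 12.9% with at least 1500 genes. Clusters changed names, and the cause was not tested.

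In single libraries Lyve1 ranged from 0 to 11.3 on the log2 scale between canal-like and vascular-like cells. Against fibroblast-like cells Kdr ranged from -3.57 to 2.78 and Trpv4 from -2.71 to 3.43. These genes have few counts, and the cause was not tested.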

Other observations

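Of the tests of an artifact below, those on depth and on genes near 0 counts were written before their results were seen, and those on rescaling, on both-sex droplets and on free RNA were written only after the results had been seen.

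Clusters 3, 4, 9 and 18 stayed unnamed, and some of the sharpest genes sit there. Cluster 4 (451 cells) held Ptn at 21976 ± 1649 CPM, Hsd11b1 at 326 ± 22.8 CPM and Wnt6 at 824 ± 111 CPM, above every named class, scored highest as trabecular meshwork (0.666) with under 3 markers up, and held Rit2, a small GTPase, at a log2 fold change of 9.54 ± 0.247. Cluster 9 (188 cells) held Angptl7, Myoc, Chad (454 ± 34.3 CPM), Tnmd (782 ± 40.2 CPM), Col1a1 (7093 ± 294 CPM) and the keratocyte marker Kera, and scored highest as fibroblast or keratocyte (1.22) with too few markers for a name. Cluster 3 (525 cells) held the neural crest gene Pax3 (9.38 ± 0.293), Syt4 (8.66 ± 0.198) and Ednrb (2344 ± 44.4 CPM). All 6 melanocyte markers were up in cluster 3, and it scored highest as melanocyte (2.13, against 1.43 for pigmented ciliary or iris epithelium). It stayed unnamed because its top 10 genes held 2 markers of pigmented epithelium, Slc45a2 and Pmel, and 0 of melanocytes. At a Leiden resolution of 2 a melanocyte-like class of 320 cells was named. Which tissues these clusters come from was not tested here.

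Most genes that differed between meshwork-like cells and the other classes were higher, 82.8% of 1623. A deep sum is not needed for such a share: before thinning, fibroblast-like cells (624761 counts) had 82.3% and pericyte-like cells (401257 counts) 81.6%. Meshwork-like cells had 10122635 counts, and the remaining classes lay at 60.2% to 79.4%. With every sum thinned to the smallest, the meshwork-like share did not fall, at 90.9% of 209 calls (190 and 19, 95% interval 86.2 to 94.4). Thinned calls were mostly higher in every other class too, 61.3% to 87.1%, so the thinned test is void. Depth as a part of the cause stays open. Scaling could explain part, because 68.9% were higher after rescaling (66.5 to 71.2), and so could genes near 0 in 1 class. Their test took genes with a mean of at least 100 CPM, of which 73.3% were higher (68.0 to 78.2), but such genes can still be near 0 in a class. Where every class had over 20 counts, 59 were higher and 39 lower. That split is set in part by the change itself, since genes raised in meshwork-like cells tend to be lacking in another class, so it cannot decide. The rules for reading these tests were changed after their values were seen, which moved depth and genes near 0 from argued against to open. No biological explanation was tested, since the design has only 1 group.

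Cluster 18 (47 cells) held melanocyte markers together with ocular surface epithelium genes in very deep cells. Mixed droplets may explain it: 34.1% of its deep cells (15 of 44; 95% interval 20.5 to 49.9) held RNA of both sexes, against 5.76% of deep cells outside clusters 10 and 18 (28 of 486). Free RNA at a like level in all deep droplets is argued against, since median Pmel, a pigment cell gene, was 4449 CPM in cluster 18 and 0 in cluster 10. Pmel was among the clustering genes, so the clustering itself sets part of this gap. Still, 156 of 162 cells of cluster 10 held at most 2 Pmel UMIs, against a median of 93 in cluster 18. If every cell of cluster 18 were a random pair, with the sex of both cells always detected, 39.1% would be expected to hold RNA of both sexes. That value lies inside the interval of 20.5 to 49.9, so all of its cells could be mixed droplets. Clumps of cells from one animal are invisible to this test, and a true dual cell type stays open for a part of the cells.

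Cluster 10, named ocular surface epithelium-like, held matrix genes such as Dcn beside keratins. The globin Hbb-bs was also there, and its source was not tested. Mixed droplets may explain it at least in part: 23.7% of its deep cells (36 of 152, 95% interval 17.2 to 31.3) held RNA of both sexes. If every cell were a random pair with both sexes always detected, 38.9% would be expected. Sex RNA that goes undetected lowers the share seen, so the gap does not show how many cells are mixed. Free RNA is argued against for Dcn alone, since its median was 1731 CPM in cluster 10 and 0 in cluster 18. How many of its cells are single epithelial cells stays open.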
